A study of Homo sapiens with 6 samples.

How the data were processed

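Gene expression was measured on 1-colour oligonucleotide arrays in Huh7 cells, an established human hepatocellular carcinoma cell line. The cells were in logarithmic growth. Total RNA was extracted with Trizol and turned into biotin-labelled antisense RNA by Affymetrix's standard procedure, per the labels' protocols. The labels form 2 groups of 3 arrays each, control cells and cells in which KCa3.1 was silenced. How the channel was silenced is not stated in the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

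The values were made by the authors with RMA, which corrects the background, normalises the arrays by quantiles and summarises the probes of a probe set, per the submitters' processing notes, which give no version. The deposited table holds log2 values that lie near 0, so each probe set had been centred after RMA. The log base was taken from RMA's usual output and is not stated otherwise. The scale and centring were worked out from the values. In all 49395 probe sets the signs of the 6 arrays fit a median of 9 arrays set to 0, and in 28686 they also fit a median of 7. The baseline is therefore taken to be a median over 9 arrays, of which 6 are analysed here and the other 3 are not analysed here. The signs would also fit a larger odd number of arrays, so the number 9 is an assumption. A value of exactly 0 on at least 1 of the 6 arrays occurred in 80.6% of the probe sets. Each array held exact zeros in 17% to 21.1% of the tested probe sets, so some probe sets hold 0 on several arrays. Such ties can narrow the spread within a group, and how they arose is not known. The median of each of the 6 arrays was 0. The centring cancels in a difference between groups, and the direction of each difference is silenced minus control. It removes the expression level of every probe set, so no statement on how strongly a gene was expressed can be made. The number of arrays limits the precision, since each group has 3.

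Of the 49395 probe sets, 102 were control probe sets and were left out of the tests. Of the other 49293, 44988 carried 1 gene symbol in the platform annotation, 1832 carried several and 2473 carried none here. No symbol needed updating through its Entrez gene identifier in NCBI's RefSeq gene table (0 updated). Each gene was given the mean of its probe sets with 1 symbol, which gave 18132 genes, 6398 of them from 1 probe set and 11734 from several. Of the 1770 changed genes with several probe sets, 1 had a probe set past the threshold in the other direction. The design fixed before the data were examined had used the brightest probe set per gene, which needs levels that centred values lack. The mean over probe sets, planned as an alternative, took its place.

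Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays, with group as the term and no block, and adjusted by the Benjamini-Hochberg method. A gene or probe set was called changed at an adjusted p under 0.05, and a second count asked in addition for a fold change of at least 2. All adjusted p-values of genes are from limma. For KCNN4, the gene of KCa3.1, a two-sided exact permutation test over the 6 arrays was added, whose smallest possible p is 0.1. The script was tested on simulated data for the silenced against control comparison with 18132 genes. It called 80% of the 100 genes changed by 0.5 and 97% of the 100 changed by 1 on the log2 scale, and 9 unchanged genes. The noise was drawn for each gene on its own and few genes were changed. These shares therefore need not hold for the real arrays.

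The 37 gene lists were written before the data were examined. Each was tested with limma's camera at a preset correlation of 0.01 over all genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Of 1071 list entries 995 were measured, and the other 76 are not analysed here. Members past the threshold were counted with adjustment over all genes tested and adjusted over the list alone. No list was called with the correlation estimated from the 6 arrays (0 of 37). That loss is not due to the correlation alone. The estimate was 0.01 for integrins, close to the preset, and 0.003 for xenobiotic metabolism, below it. For these lists the adjusted p of camera still rose from 0.033 to 0.37 and from 0.0063 to 0.33. For most other called lists the estimate lay well above the preset, from 0.101 for hepatocyte transcription factors to 0.357 for glycolysis. There correlation between genes may account for part of the loss, and how much was not tested. This alternative therefore does not show by itself that correlation between genes undoes the calls, nor that the calls withstand it.

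Genes are named by a rule that was fixed in advance. It takes KCNN4, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, the 3 largest changes of each list among its members past the threshold (or the largest change where none passed), and a fixed set of genes of the cell cycle, the epithelial-mesenchymal transition, the liver and related potassium channels. Unnamed loci, open reading frames and antisense RNAs are passed over. The rule also asked for a minimum expression level, which could not be applied to centred values. Genes outside it that are named below are examples chosen after their values were seen.

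The alternatives were a replicate block, a second quantile normalisation, median centring, a robust prior, array quality weights, the most variable probe set per gene, other thresholds, an ordinary two-sample test, other forms of the list test, and leaving out each array. Cyclic loess, a prior with an intensity trend and filters on dim probe sets were not run, since they need expression levels. The robust prior without a trend and a version with specific probe sets only were chosen after seeing the data.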

Results

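Transcript levels of Huh7 cells, a human hepatocellular carcinoma line, were measured on 6 arrays, 3 of control cells and 3 of cells labelled as KCa3.1 silenced. KCa3.1 is the intermediate-conductance calcium-activated potassium channel and is encoded by KCNN4. The comparison asks which transcripts differ when the channel is silenced in these cells. Values are log2 RMA values relative to each probe set's median. Arrays of the same label correlated with r between 0.406 and 0.67 across probe sets, and arrays of different labels with r between -0.273 and 0.068, where probe sets are not independent replicates. The first principal component held 62% of the variance and separated the 2 labels, and the second held 15.2%.

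KCNN4 itself (Entrez gene 3783) was not lower in the arrays labelled KCa3.1 silenced. Its values were -0.006, 0.126 and -0.073 in the control arrays and -0.055, 0.089 and 0.011 in the silenced-labelled arrays. The group means were 0.016 ± 0.101 and 0.015 ± 0.072 (SD, n = 3 each). The difference was -3e-04, with a 95% interval of -0.157 to 0.156, which excludes a fall beyond 10.3% on this scale (limma adjusted p = 0.999, exact permutation p = 1 against a smallest possible 0.1). Its 3 probe sets gave differences of 0.021, -0.0277 and 0.0058. The levels of these probe sets relative to background are unknown, and all of them are of the kind whose probes can match other transcripts. Since the target gene did not bear out the label, all directions below are between arrays as labelled. Of the related channels, KCNN1, KCNN3 and KCNMA1 did not pass the test, with log2 changes of -0.04, -0.05 and -0.02. KCNN2 is not analysed here.

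In the silenced-labelled arrays, in which KCNN4 was not lower, AKR1B10, SULT2A1 and A2M were among the genes with the largest rises, and NTS, IGFBP1 and NPPB among those with the largest falls. The largest rise was in AKR1B10, an aldo-keto reductase, which was 6.62-fold higher (log2 change 2.73, SE 0.058, limma adjusted p = 1.3e-07). SULT2A1, a hepatic sulfotransferase of steroids and bile acids, was 5.36-fold higher, and A2M, the plasma protease inhibitor alpha-2-macroglobulin, 4.47-fold. The largest fall was in NTS, the precursor of neurotensin, which was 4.17-fold lower (log2 change -2.06, SE 0.057, limma adjusted p = 3.6e-07). IGFBP1 was 3.99-fold lower and IGFBP3 3.1-fold lower, both of which bind insulin-like growth factors.

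In all, 2418 of 18132 genes changed, 13.3% of those tested, with 1295 higher and 1123 lower (limma, adjusted p under 0.05). At least 2-fold changes were found in 118 genes, 63 higher and 55 lower, and in 224 genes, 128 higher and 96 lower, with the most variable probe set per gene in place of the mean. The median size of the change among changed genes was 0.36 on the log2 scale. In 29.3% of the genes the values of the 2 groups did not overlap, where chance gives 10%. Of 49293 probe sets 5261 changed, 2869 higher and 2392 lower, and 406 changed at least 2-fold, 235 higher and 171 lower. The count of lower genes was 745 without control replicate 3, 736 without silenced replicate 2 and 747 without silenced replicate 3. The count of changed probe sets was 3444 without control replicate 3 and 3479, 3358 and 3252 without silenced replicates 1, 2 and 3. That of higher probe sets was 1802 without silenced replicate 1 and 1765 without silenced replicate 3. That of lower probe sets was 1571 and 1429 without control replicates 2 and 3, and 1417 and 1487 without silenced replicates 2 and 3.

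**Figure D1:**
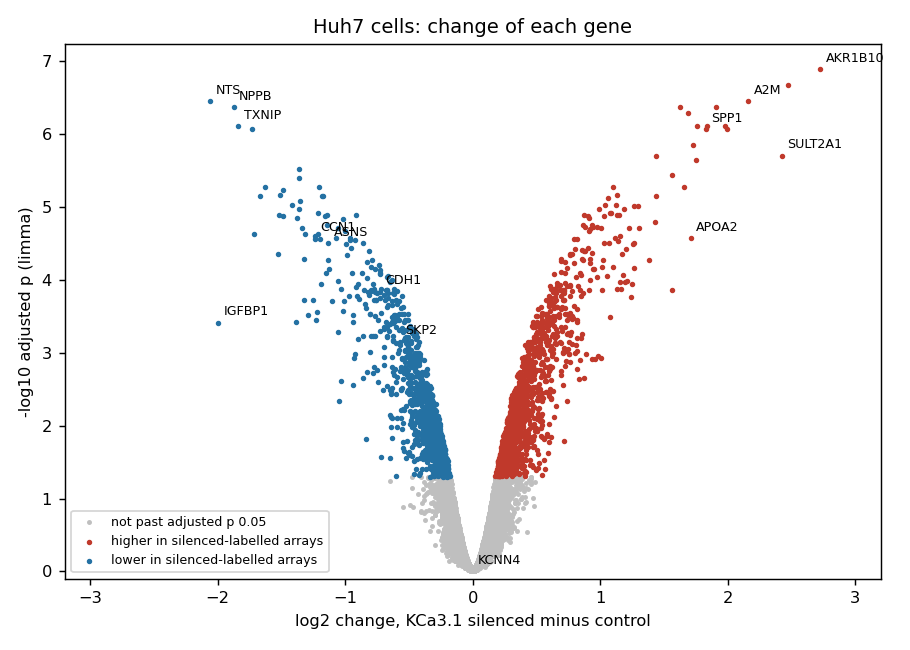
Log2 change of each of 18132 genes, silenced-labelled minus control arrays (x axis), against the negative log10 of its limma adjusted p (y axis). Red points are the 1295 genes that were higher, blue points the 1123 that were lower and grey points did not pass. KCNN4 lies at the origin.

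Among the other large rises, DACH1, a transcriptional cofactor, was 3.99-fold higher (log2 change 2.00, SE 0.072). SERPINI1, which encodes neuroserpin, rose by 1.98, the protease cathepsin E gene CTSE by 1.91, and RELN, which encodes the secreted protein reelin, by 1.84. SPP1, the gene of the matrix protein osteopontin, rose by 1.83 (SE 0.066, limma adjusted p = 8.7e-07), with all 6 of its probe sets past the threshold. BTF3L4 rose by 1.76, the fatty acid elongase gene ELOVL6 by 1.75 and the long noncoding RNA UCA1 by 1.73. AKR1B15 was 5.56-fold higher, but it is a close relative of AKR1B10 in sequence and was measured by 1 probe set, so its value is uncertain.

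Among the other large falls, NPPB, the gene of B-type natriuretic peptide, was 3.67-fold lower (log2 change -1.88, SE 0.057). TXNIP, which encodes a thioredoxin-binding protein, fell by 1.84 on the log2 scale, and CAPN2, the gene of a calcium-dependent protease subunit, by 1.73, each with all 5 probe sets past the threshold. INHBB, which encodes an activin and inhibin subunit, fell by 1.67 on the log2 scale. The keratin gene KRT23 fell by 1.53, EMP3 fell by 1.52, ALPK2 fell by 1.51 and the caveolar gene CAVIN1 fell by 1.49 on that scale. LGALS14, with a log2 change of -1.71, belongs to a cluster of similar galectin genes and was measured by 1 probe set, so its value is uncertain. IGFBP1 had the widest spread of these genes, with 1.68 ± 0.269 in control and -0.32 ± 0.462 in silenced-labelled arrays (SD, n = 3).

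SKP2, the substrate-binding subunit of an SCF ubiquitin ligase that marks CDK inhibitors for degradation, fell by 0.57 on the log2 scale (SE 0.068, limma adjusted p = 0.00071). Its cofactor CKS1B fell by 0.66 and cyclin D1 (CCND1) fell by 0.46. CDKN1A and CDKN1B, which encode the inhibitors p21 and p27, did not pass the test, with changes of -0.12 (SE 0.065, limma adjusted p = 0.3) and -0.04 (SE 0.092, limma adjusted p = 0.84). Of the 25 measured genes of the list of the SKP2 ligase and CDK inhibitors, 2 were higher, 6 lower and 17 did not pass, and 2 and 6 passed when adjusted over the list alone. The list was lower by camera (limma, adjusted p = 0.016, median change -0.085). That call was lost without control replicate 3 (adjusted p = 0.068) and without silenced replicate 2 (adjusted p = 0.079), and the adjusted p = 0.49 with an estimated correlation. MYC rose by 0.28 (SE 0.068, limma adjusted p = 0.026), and its call was lost without control replicate 1 or 2 or silenced replicate 2 or 3, where the change lay between 0.23 and 0.29.

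Genes of DNA replication were mostly lower or did not pass. Of 38 measured genes 10 were lower, 1 was higher and 27 did not pass, and adjusted over the list alone 16 were lower and 2 higher. GINS1, a subunit of the replicative helicase complex, fell by 0.52 on the log2 scale and the ribonucleotide reductase gene RRM1 fell by 0.35, while MCM6, another helicase subunit, rose by 0.60. The list was lower by camera (limma, adjusted p = 2e-04, median change -0.141), with an adjusted p = 0.43 with an estimated correlation. Of 37 genes of mitosis and G2/M, 5 were lower, 1 was higher and 31 did not pass, and adjusted over the list alone 6 were lower and 1 higher. The kinesin gene KIF4A fell by 0.43 on the log2 scale. KIF20A fell by 0.35 and had a change of -0.31, no longer past the threshold, without silenced replicate 3. The centromeric histone gene CENPA fell by 0.29, and its call was lost without control replicate 2 or 3 or any of the 3 silenced replicates, where its change lay between -0.32 and -0.24. This list was lower too (camera of limma, adjusted p = 0.0014, median -0.106), with an adjusted p = 0.14 by fry, which compares a list with no change and not with other genes, and an adjusted p = 0.49 with an estimated correlation.

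**Figure D2:**
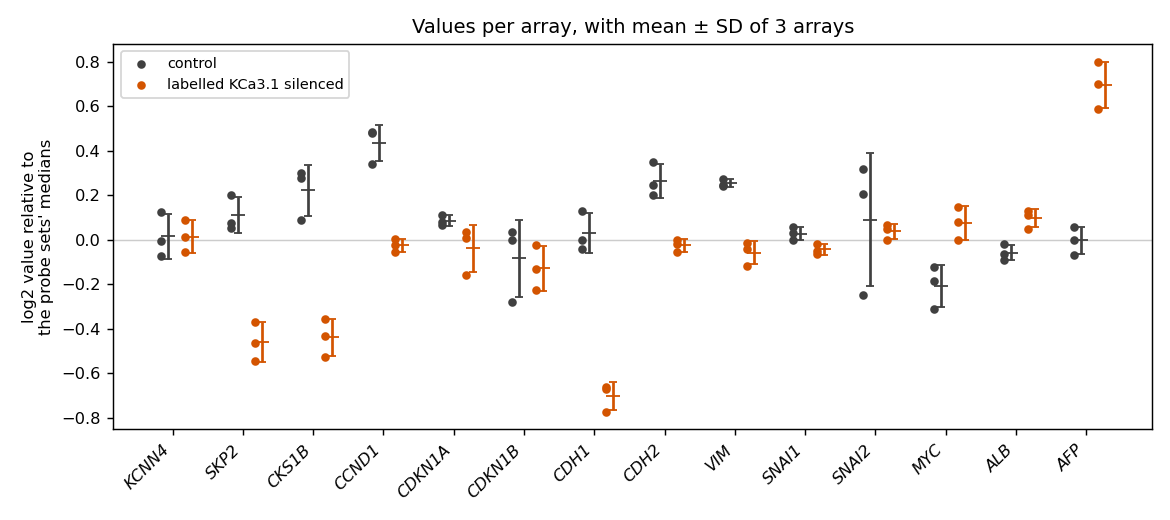
Log2 values relative to the probe sets' medians (y axis) of KCNN4 and 13 other genes (x axis) on each of the 6 arrays. Points are arrays, dark for control and orange for silenced-labelled, and the bars beside them give the mean and SD of 3 arrays. KCNN4, CDKN1B and SNAI2 overlap between the labels. SKP2, CKS1B, CCND1 and CDH1 are lower and AFP is higher in every silenced-labelled array than in every control array. CDH2, VIM, MYC, ALB, CDKN1A and SNAI1 do not overlap either, though ALB, CDKN1A and SNAI1 did not pass the test.

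The lists of epithelial and of mesenchymal genes each held more lower than higher genes in the silenced-labelled arrays. CDH1, which encodes E-cadherin, fell by 0.73 on the log2 scale (SE 0.065, limma adjusted p = 0.00015). CDH2, which encodes N-cadherin, fell by 0.29 (SE 0.059, limma adjusted p = 0.011) and vimentin (VIM) fell by 0.31 (SE 0.054, limma adjusted p = 0.0052). SNAI1 and SNAI2, which encode repressors of E-cadherin, did not pass the test, with changes of -0.07 and -0.05. Of 28 measured genes of epithelial junctions 8 were lower, 1 was higher and 19 did not pass, with 8 and 1 when adjusted over the list alone. The desmosomal cadherin gene DSC2 fell by 0.78 and the keratin gene KRT19 fell by 0.50 on the log2 scale. Of 31 mesenchymal genes 13 were lower, 2 were higher and 16 did not pass, with 13 and 2 when adjusted over the list alone. TAGLN, the gene of an actin-binding protein of smooth muscle, was 2.6-fold lower, and the matricellular genes CCN1 and CCN2 were 2.36-fold and 2.32-fold lower. Both lists were lower by camera (limma, adjusted p = 5.4e-05 for junctions, median -0.145, and 1.2e-05 for mesenchymal genes, median -0.101). For each of them the adjusted p = 0.26 with an estimated correlation.

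Targets of TGF-beta and YAP, 2 regulators of matrix and growth genes, were lower in 10 of 28 measured genes and higher in 1, and 17 did not pass. Adjusted over the list alone, 14 were lower and 1 was higher. Beside CCN1 and CCN2, which are also on the mesenchymal list, WWTR1, which encodes the YAP relative TAZ, fell by 0.73 on the log2 scale. The list was lower by camera (limma, adjusted p = 5.4e-05, median -0.164), with an adjusted p = 0.37 with an estimated correlation. Of 24 genes of integrins and focal adhesion 5 were lower, none was higher (0) and 19 did not pass, with the same counts when adjusted over the list alone. ILK, the integrin-linked kinase gene, fell by 0.43 and the talin gene TLN1 fell by 0.36 on the log2 scale. The zyxin gene ZYX fell by 0.29, and its call was lost without control replicate 2 (change -0.26) and without silenced replicate 2 (change -0.23). This list was lower (camera of limma, adjusted p = 0.033, median -0.051). Its adjusted p was 0.061 without control replicate 3, 0.082 and 0.053 without silenced replicates 2 and 3, 0.081 with specific probe sets and 0.059 by ranks, and the adjusted p = 0.37 with an estimated correlation.

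Several liver genes were higher in the silenced-labelled arrays. Of 40 plasma proteins made by hepatocytes 16 were higher, 5 were lower and 19 did not pass, and adjusted over the list alone 18 were higher and 7 lower. The high-density lipoprotein gene APOA2 was 3.28-fold higher (log2 change 1.71, SE 0.113), the antithrombin gene SERPINC1 2.95-fold and APOA1 2.2-fold. Albumin (ALB) did not pass the test, with a change of 0.16 (SE 0.054, limma adjusted p = 0.1). VTN, CP, APOH, F2 and ITIH2 were the 5 lower genes. The list was higher by camera (limma, adjusted p = 0.00019, median 0.123), with an adjusted p = 0.49 with an estimated correlation. Of 19 hepatocyte transcription factors 7 were higher, 0 lower and 12 did not pass, also when adjusted over the list alone. FOXA1 rose by 0.66 and GATA6 by 0.55. ONECUT2 rose by 0.50, and its call was lost without control replicate 2 or 3 or silenced replicate 1 or 2, where its change lay between 0.40 and 0.50. This list was higher (camera of limma, adjusted p = 0.0025, median 0.094), with an adjusted p = 0.39 with an estimated correlation.

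Of 37 genes of the xenobiotic, bile acid and amino acid metabolism of the liver 10 were higher, 2 were lower and 25 did not pass. Adjusted over the list alone, 12 were higher and 5 lower. TDO2, which encodes a dioxygenase that degrades tryptophan, was 3.09-fold higher, the alcohol dehydrogenase gene ADH6 2.17-fold and the cytochrome gene CYP3A5 2.04-fold. The list was higher by camera (limma, adjusted p = 0.0063, median 0.022). Its adjusted p was 0.077 with specific probe sets and 0.12 by ranks, and the adjusted p = 0.33 with an estimated correlation. AFP, the fetal liver protein alpha-fetoprotein, rose by 0.70 (SE 0.068, limma adjusted p = 0.00024). On the list of oncofetal and hepatocellular carcinoma genes 10 of 27 were higher, 3 were lower and 14 did not pass, among them SPINK1, 2.46-fold higher, and PEG10, 1.87-fold higher. That list was not called (camera of limma, adjusted p = 0.073, median 0.072).

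Several genes of fatty acid synthesis and storage were higher. Of 26 measured genes 10 were higher, 2 were lower and 14 did not pass, and adjusted over the list alone 14 were higher and 2 lower. Beside ELOVL6, the glycerol-phosphate acyltransferase gene GPAM rose by 0.87 and DGAT2, which encodes an enzyme of triglyceride synthesis, by 0.80. PLIN2 and AGPAT2 were the 2 lower genes. The list was higher by camera (limma, adjusted p = 5.9e-06, median 0.183), with an adjusted p = 0.37 with an estimated correlation. Of 28 genes of the NRF2 and oxidative stress list 12 were higher, 0 lower and 16 did not pass, and adjusted over the list alone 13 were higher and 2 lower. Beside AKR1B10, the sulfiredoxin gene SRXN1 was 2.19-fold higher and the glutathione peroxidase gene GPX2 1.91-fold. This list was higher (camera of limma, adjusted p = 3.5e-06, median 0.136), with an adjusted p = 0.37 with an estimated correlation.

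Several stress response genes were lower. On the list of the unfolded protein response and ATF4 targets 11 of 34 genes were lower, 1 was higher and 22 did not pass, and adjusted over the list alone 16 were lower and 1 higher. ASNS, which encodes asparagine synthetase, was 2.19-fold lower, the amino acid transporter gene SLC3A2 fell by 0.63 and the lipoprotein receptor gene VLDLR fell by 0.60 on the log2 scale. The list was lower by camera (limma, adjusted p = 5.9e-06, median -0.166), with an adjusted p = 0.42 with an estimated correlation. Of 20 hypoxia-inducible genes 9 were lower, 0 higher and 11 did not pass, and adjusted over the list alone 10 were lower and 1 higher. STC2, the gene of the hormone stanniocalcin 2, was 2.22-fold lower, DDIT4, an inhibitor of mTORC1 signalling, fell by 0.64 and the mitophagy receptor gene BNIP3L fell by 0.56 on the log2 scale. This list was lower (camera of limma, adjusted p = 2.9e-05, median -0.187), with an adjusted p = 0.39 with an estimated correlation.

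Of 22 glycolysis genes 3 were lower, 1 was higher and 18 did not pass, with the same counts when adjusted over the list alone. The phosphoglycerate kinase gene PGK1 fell by 0.63 and PFKFB4 fell by 0.35 on the log2 scale, while the lactate dehydrogenase gene LDHB was 2.28-fold higher. The list was lower by camera (limma, adjusted p = 0.031, median -0.079). Its adjusted p was 0.12 and 0.061 without control replicates 2 and 3, 0.1 without silenced replicate 2 and 0.15 by fry, and the adjusted p = 0.64 with an estimated correlation. Of 33 ribosomal protein genes 1 was lower, RPS16, which fell by 0.21, and 32 did not pass, and none passed when adjusted over the list alone (0). The call of RPS16 was lost without control replicate 2 or 3 or any of the 3 silenced replicates, where its change lay between -0.23 and -0.19. The ribosomal list was lower by camera (limma, adjusted p = 0.021, median -0.068). Its adjusted p was 0.069 and 0.061 without control replicates 2 and 3, 0.072 without silenced replicate 2, 0.25 with the most variable probe set and 0.57 with specific probe sets, and the adjusted p = 0.63 with an estimated correlation.

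**Figure D3:**
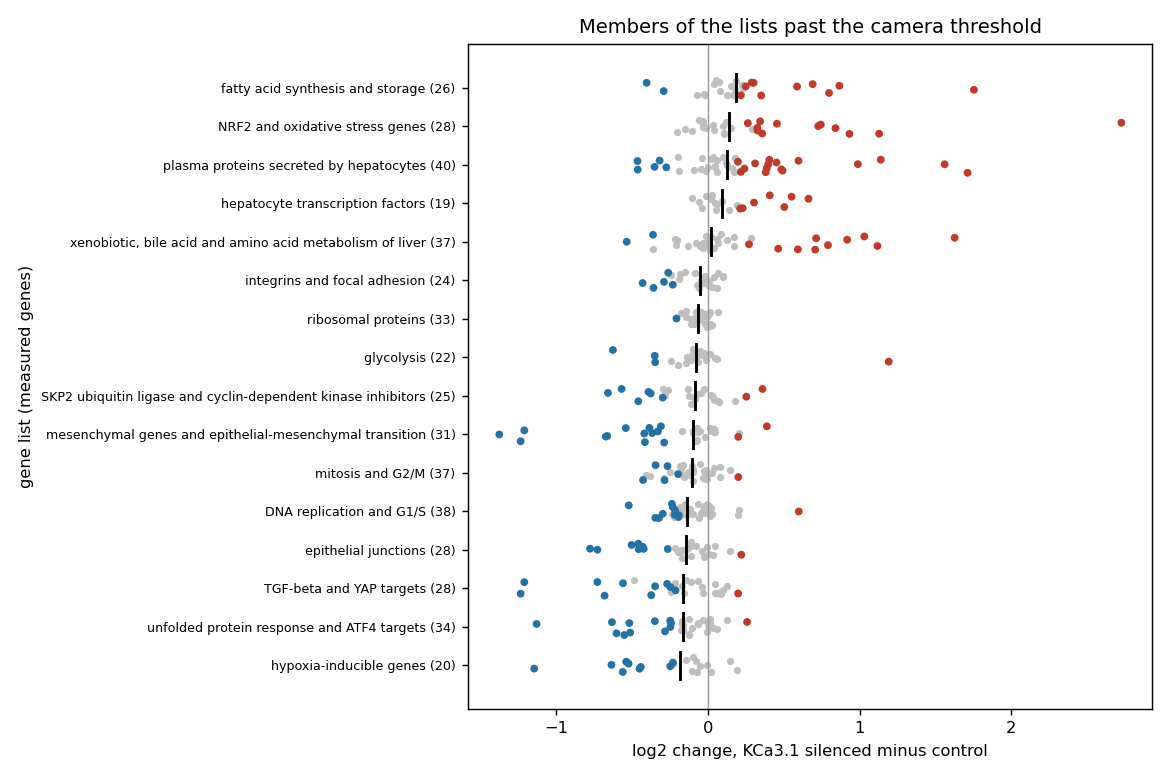
Log2 change, silenced-labelled minus control arrays (x axis), of the measured genes on each of the 16 called gene lists (y axis, number of genes in parentheses). Red and blue points passed limma's adjusted p of 0.05 over all genes and grey points did not, and black bars are list medians, from -0.187 for hypoxia-inducible genes to 0.183 for fatty acid synthesis.

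Of the 37 lists 16 were called, 5 higher and 11 lower, and 21 were not. A grouping of the arrays that mixes the labels called 17 lists. On the calcium entry, stores and sensors list 4 of 24 genes were higher and 5 lower, and the calcium-binding protein genes S100A6, S100A11 and S100A10 fell by 0.80, 0.77 and 0.67 on the log2 scale. Of 17 related potassium channels 1 was higher, KCNJ16, with a change of 0.73. Its 2 probe sets gave 1.179 and 0.28, the second not past the threshold. On the matrix protease and invasion list 3 of 33 genes were higher, SPP1, MMP11 (0.87) and PLAU, and 8 were lower, with MMP7 at -0.79. The probe sets of MMP7 ranged from -1.343 to 0.009. Of 22 p53 targets 4 were lower and 2 higher, with DDB2 at -1.05, TRIAP1 at -0.96 and TP53INP1 at 0.62. The probe sets of TP53INP1 gave 1.137 and 0.106, the second not past the threshold. Of 24 genes of fatty acid oxidation and PPARA targets 3 were lower, among them ANGPTL4 (-1.29) and CPT1A (-0.45), and 1 was higher. That list passed, lower, without control replicate 1 (camera of limma, adjusted p = 0.041 against 0.22 with all arrays). Inflammation and acute phase genes went both ways, with 6 higher and 6 lower of 33, IL18 at -0.94 and SAA1 at 0.89. The median, the mean and the camera direction did not share a sign in 7 lists that were not called, among them inflammation, cholesterol synthesis and apoptosis. On the 21 lists that were not called, counts adjusted over the list alone differed from those over all genes by at most 4 genes per direction.

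Markers of other cell types were measured as a check. Of 19 leukocyte markers 2 were higher, LCP1 (0.41) and LYZ (0.34), and 0 were lower. The call of LYZ was lost without control replicate 1 (change 0.29), control replicate 3 (0.34) or silenced replicate 3 (0.26). Of 18 markers of fibroblasts and stellate cells, COL1A2 rose by 0.55 and TAGLN fell by 1.38 on the log2 scale, and 16 did not pass. Of 17 endothelial markers none passed (0 by limma), and ESAM had the largest change, -0.27. Without control replicate 2 ESAM passed, with a change of -0.35. None of these 3 lists was called (camera of limma, adjusted p = 0.6 for leukocytes, 0.99 for fibroblasts and 0.69 for endothelial cells). Of the 102 control probe sets 0 passed limma's threshold, and 15 had an unadjusted p under 0.05. The spikes added before hybridisation were at 0.076 ± 0.015 on the control arrays and -0.038 ± 0.046 on the silenced-labelled ones (SD, n = 3), with no overlap (exact permutation p = 0.1, the smallest possible).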

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

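The specific probe sets and the robust prior were chosen after the data were seen, and all other alternatives before. No called list and no called gene among the named ones turned direction under any alternative run for it (0). The signs of the other called genes were checked only with 1 array left out. Among lists that were not called, fry took the direction opposite to camera for inflammation, MAPK and PI3K feedback and fibroblast markers. Of 832 comparisons of a count or a list with its alternatives 751 kept their side of the threshold or stayed within 1.5 times, and of 1641 for named genes 1567 did, 71 lost the call and 3 gained it. These tallies include 51 and 128 comparisons by median centring, which could not change. Cyclic loess, the prior with a trend and the filters on dim probe sets were not run, since centred values carry no level, and signal over background is unknown for the same reason. Median centring moved nothing, since all array medians were 0, so it says nothing about stability. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated with r of -0.096, -0.069 and -0.04. Higher values were found in another order. Control 1 with silenced 2 gave an r of 0.373, and control 2 with silenced 3 and control 3 with silenced 1 gave 0.381 each. The remaining pairs lay between -0.379 and -0.249. What the arrays of such a pair may share is not stated in the labels, and no fit took this order into account. With the numbers as a replicate block 2065 genes were called, no count or list changed its call, and of the named genes 6 lost it and 1 gained it. The causes of the changes below were not tested, except that a stricter threshold lowers a count by construction. Leaving out 1 array did not always lower a count: up to 1167 genes were then lower, against 1123 with all arrays.

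At an adjusted p under 0.01 (limma), 1303 genes were called, 721 higher and 582 lower, and 2516 probe sets, 1385 higher and 1131 lower. With a fold change of at least 1.5 in place of 2, 456 genes passed, 263 higher and 193 lower, and 1538 probe sets, 863 higher and 675 lower. An ordinary two-sample test called 1289 genes, 701 higher and 588 lower, and 2510 probe sets, 1342 higher and 1168 lower. With the most variable probe set per gene 224 genes changed at least 2-fold, 128 higher and 96 lower, and the ribosomal protein list lost its call (limma, adjusted p = 0.25). Specific probe sets ended the calls of the integrin (0.081), xenobiotic metabolism (0.077) and ribosomal protein (0.57) lists.

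With an estimated correlation 0 lists were called, also where the estimate was close to the preset 0.01 (integrins, 0.01) or below it (xenobiotic metabolism, 0.003). For most other called lists the estimate was well above the preset, up to 0.357 for glycolysis. Limma's adjusted p was then 0.49 for the SKP2 list, 0.43 for DNA replication, 0.49 for mitosis, 0.26 for epithelial junctions, 0.26 for mesenchymal genes, 0.37 for integrins, 0.49 for plasma proteins, 0.39 for hepatocyte transcription factors, 0.33 for xenobiotic metabolism, 0.37 for fatty acid synthesis, 0.64 for glycolysis, 0.39 for hypoxia, 0.63 for ribosomal proteins, 0.42 for the unfolded protein response, 0.37 for NRF2 and 0.37 for TGF-beta and YAP. This was the highest of 17 alternatives for each of the 16 lists. The lowest was 0.0042 for the SKP2 list, 0.0056 for glycolysis, 0.0098 for integrins, 0.005 for ribosomal proteins and, by fry, 0.0015 for xenobiotic metabolism. Fry asks another question, whether a list's genes move one way on balance, with no comparison to other genes. By fry the mitosis (0.14) and glycolysis (0.15) lists did not pass and the oncofetal (0.003) and interferon (0.04) lists did. Ranks lost the integrin (0.059) and xenobiotic (0.12) lists and gained the proteasome list (0.039), which array quality weights gained too (0.041).

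With 1 array left out, limma called between 1641 and 2289 genes, of which 1605 to 1997 were among the 2418, and all 2418 kept their sign. Between 736 and 1167 genes were lower, 3252 to 4592 probe sets changed, 1765 to 2314 were higher and 1417 to 2278 lower. The adjusted p ranged from 0.0042 to 0.079 for the SKP2 list, from 0.0098 to 0.082 for integrins, from 0.0056 to 0.12 for glycolysis and from 0.0056 to 0.072 for ribosomal proteins. It ranged from 0.041 to 0.56 for fatty acid oxidation, which passed without control replicate 1 (0.041), and from 0.03 to 0.27 for the interferon list, which passed without control replicate 1 (0.041) and silenced replicate 1 (0.03). It ranged from 0.022 to 0.27 for immediate early genes, which passed without control replicate 1 (0.022) and silenced replicate 3 (0.03), and from 0.011 to 0.31 for the proteasome list, which passed without control replicate 1 (0.011) and silenced replicate 1 (0.038).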

Other observations

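The tests on wrong labels, on the KCNN4 interval, on fibroblasts and on the hybridisation spikes were chosen after their values were seen, and the actin list took its final form after a first result, while those on neighbouring genes and on other splits were written before.

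On a list of actin cytoskeleton genes, many of them targets of the transcription factor SRF, 10 of 21 measured genes were lower in the silenced-labelled arrays, in which KCNN4 was not lower. The list was written after the large falls had been seen, and genes among the 40 largest falls were left out. VCL, TLN1 and ZYX, which another list holds, were left out only after a first result with them. With them, over 24 genes, the median was -0.257 and camera's evidence for a lower list was stronger than that given below. Of the remaining 21, 1 was higher and 10 did not pass (limma), and the median log2 change was -0.252. FHL2, which encodes a LIM-domain cofactor, had a change of -1.01 (SE 0.096), the tropomyosin gene TPM4 -0.80 and the calponin gene CNN2 -0.72. Cytoplasmic gamma-actin (ACTG1) was at -0.43 and the light chain gene MYL9 at -0.42, while ACTB did not pass at -0.14 and MYH10 was higher at 0.33. SRF itself had a change of -0.08 and did not pass.

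Signalling genes on lists that were not called went both ways. On the MAPK and PI3K feedback list 6 of 28 genes were higher and 6 lower, with the phosphatase gene DUSP1 at -0.82, IER3 at -0.76 and the insulin receptor substrate gene IRS2 at -0.54. Of 37 interferon-stimulated genes 6 were lower and 1 was higher, with ISG20 at -0.48 and ISG15 at -0.43 (camera of limma, adjusted p = 0.08). Of 21 WNT pathway targets 4 were lower and 2 higher, with DKK1 at -0.48. Among 26 apoptosis regulators BAK1 was at -0.47 and CASP6 at 0.35, with 4 lower and 2 higher. Of 18 immediate early genes JUNB had the largest change, -0.57, and of 31 autophagy and lysosome genes ULK1, 0.44.

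The target gene KCNN4 did not differ between the labels, although 2418 other genes did. A single array with the wrong label is argued against by the correlations, since every array correlated better with its own label, by a mean r of at least 0.598. Whether a whole group carried a wrong label cannot be seen from these correlations, since its arrays would still correlate with each other. Whether the KCNN4 probe sets carry signal of the transcript stays open: the 95% interval of the change reached from -0.157 to 0.156, and centred values hold no level against background. If these probe sets sit at background, silencing could be present and not visible. A silencing that acts on the protein, or that was incomplete or had been compensated, may also leave the transcript as it is, and none of these was tested.

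Several contractile genes, such as TAGLN, were lower and several liver genes, such as APOA2, were higher, while most members of each liver list did not pass or were lower. Fibroblasts mixed into the control cultures are argued against, since the 16 other fibroblast markers had a median change of 0.004, with COL1A1 at -0.08 and COL1A2 higher at 0.55. A candidate explanation, offered as a hypothesis, is a difference in actin and SRF activity between the cultures, as cell density or attachment may give. The actin list was lower with camera p = 5.2e-08, and p = 0.0074 with an estimated correlation, against a lowest p of 2e-04 in the other 9 of 10 splits of the arrays, but it was drawn up after those falls had been seen and reshaped after a first result, so these values describe the pattern and lend the hypothesis no support. The hypothesis stays open, the rises of liver genes were not part of the test, and the labels give no density.

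The number of changed genes was the third pattern weighed. No run of 51 neighbouring genes reached the bound of 0.2 set for gains or losses of chromosome segments between the cell populations. The largest median change was 0.115 in size, on chromosome 6. That window still lay beyond the 95th percentile of 1000 shuffles of the gene order, 0.093. In all 16 windows did, 14 of them higher on chromosome 6 and 2 lower on chromosome 19 (around ZNF257 and ZNF676, -0.096). The share of higher genes ranged from 2.3% on chromosome 19 to 14% on chromosome 4. Levels are unknown, so genes without signal could not be left out, and they can draw a median toward 0. A short segment cannot move a median over 51 genes. The windows therefore cannot exclude gains or losses, and smaller regional shifts are not excluded. Separate hybridisation of the groups stays open: the hybridisation spikes differed by -0.114 without overlap, but 0 of their 18 probe sets passed limma, and batch and label cannot be told apart. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05.

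By split, the real one gave 2418 genes, 118 genes of at least 2-fold and 5261 probe sets, and it was the 1 split of 10 with as many of each. The highest of the other 9 was 0 for all of these by limma, with up to 1055 genes at an unadjusted p under 0.05 against 4467 in the real split. For the lists, 16 were called in the real split and 17 in another, that of control replicate 1 and silenced replicates 2 and 3 against the rest, so that 2 of the 10 splits gave as many. Camera's preset correlation thus called as many lists in a split that mixes the labels.

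Among the 118 genes changed at least 2-fold, the mean of the silenced-labelled arrays lay nearer to the baseline, taken to be of 9 arrays, in 74 and that of the control arrays in 44. Of the 2473 probe sets without a gene symbol 122 were higher and 100 lower, 15 of them higher by at least 2-fold.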
